A study of Gallus gallus with 13 samples.

How the data were processed

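Total RNA from 13 cultures of primary chicken embryo fibroblasts was hybridised to Affymetrix chicken arrays, 15 µg per culture with an RNA integrity number of at least 9.7 per the labels. The deposited values are probe set signals, an intensity on a linear scale, which the authors computed with Affymetrix Expression Console 1.1 and its PLIER method. The background and probe options and the scaling between arrays are not given in the sources used here. Column medians and quartiles differed between arrays, so the deposited intensity was not quantile normalized over all probe sets, and no further normalization was applied here. Of 38535 probe sets, 37693 had a chicken ID. The 153 control and reporter probe sets served as quality measures, and the 689 other probe sets without a chicken ID were not used in the comparisons. Of the values, 2969 (0.593%) were exactly 0.

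An offset of 16 was added and log2 taken. Probe sets whose mean log2 value lay under the 25th percentile, a signal of 22.7, were left out, and 28270 were tested. Of these, 21078 had 1 gene symbol and stood for 11498 genes. Probe sets with several symbols (177 of all) or none (10350) were counted but not named. A gene was represented by its probe set with the highest mean, and 5716 genes had more than 1 tested probe set. Gene symbols came from the array annotation. The chicken genome annotation served to assign probe sets to the W, Z and other chromosomes, and no coordinates were used.

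The 4 groups were fitted as group means over 13 arrays with limma 3.58.1 (lmFit, then eBayes with a trend on mean level) in R 4.3.3, with 9 residual and 4.33 prior degrees of freedom. Each arrested group was compared with cycling cells, and the arrested groups with each other. The interaction is the effect of starvation in confluent cells minus that in sparse cells. Tests were moderated, two-sided and adjusted over all tested probe sets by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.

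For named genes, each comparison with cycling cells took the 8 genes highest and the 8 lowest by log2 change. They had to pass, show no overlap between the values of the 2 groups and bear neither a LOC nor an ORF symbol. Values of 3 and 3 arrays are fully apart by chance in 10% of cases. Up to 4 members with the smallest adjusted p were added for each list that passed, with 15 genes named in advance, of which 13 were measured; GAS1 has no named probe set on the array, and 1 gene is not reported here. The other comparisons and the interaction took the 5 highest and 5 lowest. Of 324 gene comparisons named in this way, over 171 genes, 4 had another tested probe set that passed in the opposite direction.

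Gene lists, 31 in all, were tested with camera from limma, with a preset correlation of 0.01 between genes and 1 probe set per gene, and adjusted over the lists within each comparison. Camera with a correlation estimated from the residuals and fry, also from limma, were run beside it. These lists, the comparisons, the rule for named genes and the alternatives were set before the data were examined, except that the W-linked level as a covariate and the joint removal of cycling replicate 3 and contact-inhibited replicate 1 were chosen after seeing the data. The other alternatives were arrays centred on their median, quantile normalization, offsets of 1 and 64, no filter and a filter at the median, eBayes without trend, array weights, the mean of all probe sets of a gene, a fit of the compared arrays alone, a replicate block, and the omission of each array in turn. The replicate numbers were not treated as pairs: residuals of arrays with the same number correlated at -0.293 to 0.382 over 18 pairs, and 4 of 12 arrays correlated best with one of their own number.

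The procedure was tested on simulated arrays with the mean and residual spread of the real probe sets, to which changes were added at 66 or 67 probe sets for each size of change. A 2-fold change was called for 80.6%, 71.6% and 79.1% of changed probe sets in the comparisons of contact-inhibited, serum-starved and doubly arrested with cycling cells. A 4-fold change was called for 98.5%, 97.0% and 100% of them, and a 1.5-fold change for 14.9%, 13.4% and 16.4%, with 9, 4 and 9 false calls among 28270 probe sets. Far more probe sets were called in the real comparisons, and the simulated noise was independent between probe sets. The shares called and the false calls may therefore differ in the real tests.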

Results

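Primary chicken embryo fibroblasts were profiled on 13 Affymetrix chicken arrays in 4 groups. The cells came from White Leghorn embryos at day 10 and were kept at 41.5 °C for fewer than 10 passages. Cycling cells (3 arrays) were harvested while growing in 5% serum. Contact-inhibited cells (4 arrays) had filled the dish and received fresh medium. Serum-starved cells (3 arrays) were taken from growing cultures into medium with no serum. The last group (3 arrays) was confluent and then deprived of serum. The design asks how each route out of the cell cycle changes the transcripts of these cells relative to cycling cells. The labels call the arrays biological replicates but do not say whether they came from separate embryos, so p-values measure the spread between these arrays. The number of arrays limits the precision of every value. Median signal per array lay between 52.1 and 68.9, and mean signal between 337 and 371. Changes are on the log2(signal + 16) scale, which understates the change of dim genes, and are given with their standard error. Signals are means ± SD over the arrays of a group.

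The cycling, contact-inhibited and starved arrays separated in the first 2 principal components, and the 2 starved groups adjoined each other. On the first component serum-starved arrays lay at -14.7 to 10.1 and doubly arrested arrays at -29.1 to -24.4. The first component held 38.4% of the variance and set the cycling arrays apart. The second held 27.2% and set the 4 contact-inhibited arrays, at -50.3 to -44.4, apart from the 6 starved arrays, at 26.0 to 40.2. Over the tested probe sets, arrays of one group correlated at 0.941 to 0.993 and arrays of different groups at 0.869 to 0.986. In total 2991 probe sets were called in the same direction in all 3 arrested groups against cycling cells. Of these, 1733 were higher (760 genes) and 1258 lower (810 genes), where independent lists of the same sizes would share 94.6 and 35.8. The 3 comparisons share their 3 cycling arrays, too few to be divided between them, so that chance value is too low by an unknown amount. Without serum-starved replicate 3 the count was 1720, with array weights 4813, and with the W-linked level described below as a covariate, chosen after seeing the data, it was 1773.

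**Figure D1:**
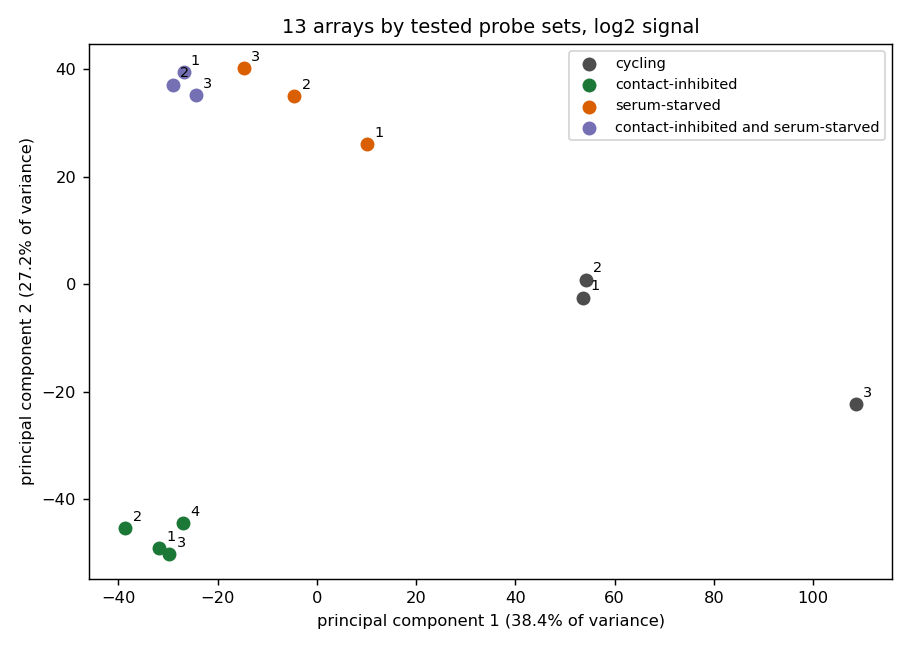
Principal components 1 and 2 of the 13 arrays (log2 signal of the tested probe sets, share of variance in percent on each axis), with each point an array labelled by its replicate number and coloured by group. Cycling replicate 3 lies at 109 on the first axis, against 53.6 and 54.2 for the other cycling arrays.

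Some arrays differed in ways that the growth conditions do not name. HINTW, a gene of the female-specific W chromosome, had a signal of 2646 to 3358 in the cycling arrays and 1188 to 1311 in contact-inhibited replicates 2 to 4. It had 84.3 in contact-inhibited replicate 1 and 428 in serum-starved replicate 1. In the 5 remaining starved arrays it was at 0 to 3.08. The mean log2 level of 22 W-linked probe sets likewise lay at 7.07 to 7.30 in the cycling arrays and contact-inhibited replicates 2 to 4, at 6.28 in contact-inhibited replicate 1, and at 5.98 to 6.66 in the starved arrays. Single W-linked genes could go the other way: NEDD4L had 293 to 515 in the starved and 199 to 226 in the cycling arrays, and MBD2 1325 to 2200 and 799 to 1315. The W-linked level therefore moves with serum removal in each comparison of starved with unstarved cells. As a covariate it widened the standard errors of serum-starved and doubly arrested against cycling cells by a median factor of 1.42 and 1.51. A call lost with it therefore does not by itself show that the W-linked difference explains the change. For some genes, such as CDKN1A and RBP7 below, the change shrank although its standard error did not widen. Lost precision does not account for the shrinkage at those genes. The covariate is fitted to differences within groups, which rest mainly on contact-inhibited replicate 1 and serum-starved replicate 1. The latter had 6.66, against 5.98 and 6.04 in the other serum-starved arrays. Contact-inhibited replicate 1 also stood apart in CDKN1A (4405) and RBP7 (642). Values adjusted in this way therefore depend on these arrays, and the shrinkage does not show that the W-linked difference explains the change. Cycling replicate 3 differed from the mean of cycling replicates 1 and 2 by at least 2-fold at 2753 probe sets, against 70 between replicates 1 and 2. Its actin 3'/5' signal ratio was 2.41, and the other 12 arrays lay between 1.27 and 1.89.

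**Figure D2:**
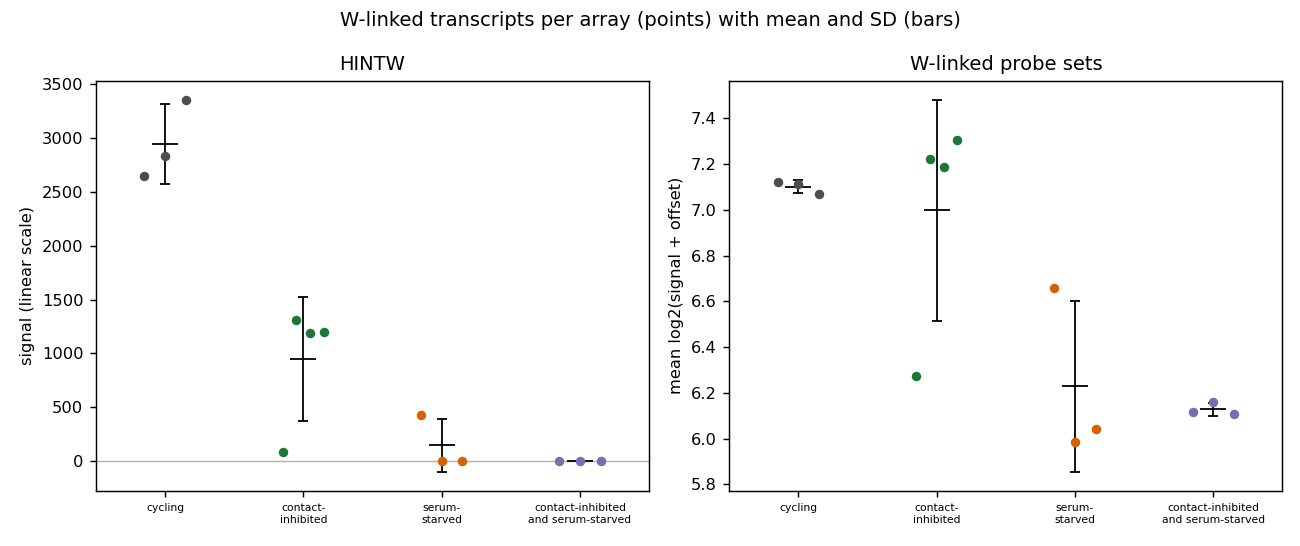
Signal of HINTW (left, linear scale) and mean log2(signal + 16) of 22 W-linked probe sets (right) for each array, as points by group, with the group mean and SD as bars. Contact-inhibited replicate 1, at 84.3 and 6.28, lies with the starved arrays and not with the other contact-inhibited arrays.

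The carriers EXFABP and FABP4 and the carbonic anhydrases CA9 and CA12 were among the genes that rose most in contact-inhibited cells. EXFABP, a secreted lipocalin that binds fatty acids, rose from 244 ± 58.7 (SD, n = 3) to 9732 ± 1318 (SD, n = 4), a log2 change of 5.24 ± 0.19 (limma adjusted p = 1.13e-09). FABP4, the fatty acid carrier of adipocytes and macrophages, rose from 201 ± 79.6 to 9009 ± 4559 (5.22 ± 0.56). CA9 and CA12 rose by 5.05 ± 0.26 and 3.92 ± 0.28, and the cross-linking enzyme TGM2 by 3.87 ± 0.11. FAM180A was the gene with the highest change, from 20 ± 3.83 to 2528 ± 411 (6.13 ± 0.15), and the secreted peptides PROK2 and OSTN rose by 4.01 ± 0.18 and 3.92 ± 0.54. Several of these genes were lower in contact-inhibited replicate 1 than in replicates 2 to 4: its signal was 659 for OSTN and 811 for CA9. Without it OSTN rose by 4.65.

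DKK4, RGS20 and ID1 fell most in contact-inhibited cells. The Wnt antagonist DKK4 fell from 4832 ± 715 to 42.0 ± 10.4 (-6.39 ± 0.25) and ID1, a dominant negative partner of helix-loop-helix factors and a target of BMP signalling, from 5668 ± 878 to 95.3 ± 2.92 (-5.66 ± 0.15). RGS20, a regulator of G protein signalling, fell to 13.2 ± 1.32 (-5.76 ± 0.11). The sarcomeric genes MYL4 (-5.29 ± 0.13) and MYH15 (-5.11 ± 0.24), the desmosome gene PKP2 (-4.99 ± 0.20) and the protease inhibitor SERPINB2 (-4.91 ± 0.34) fell as well. MGP, an inhibitor of calcification, fell from 4663 ± 164 to 204 ± 103 (-4.51 ± 0.37). The skeletal muscle list as a whole did not pass: of 16 genes 5 fell and 2 rose (adjusted p = 0.218). Where a group mean lies under 22.7, the signal that served as the filter on mean level, the fold depends on the offset. Among the genes named in this report this holds in cycling cells for FAM180A, GATD3AL2, CPXM2, COCH, CUTAL, FGA and ACAN. In contact-inhibited cells it holds for RGS20, MYL4, MYH15, PKP2, HSPB8, FBLN5 and RORA. It holds in serum-starved cells for DKK4, RGS20, PROK2 and ACAN, and in doubly arrested cells for HINTW, DKK4, RGS20, MYH15, ADAMTSL3 and ACAN. Genes named only in the closing observations are marked there.

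Genes for growth and division fell together in contact-inhibited cells. Of 46 measured ribosome biogenesis genes, 39 fell and 0 rose (40 and 0 adjusted over the list alone), with a median of -1.06. NOLC1 (-1.84 ± 0.14), NOP16 (-2.08 ± 0.18), NHP2 (-1.87 ± 0.18) and EBNA1BP2 (-1.28 ± 0.12) were among them. Of 45 genes of DNA replication and S phase, 32 fell and 0 rose (33 and 0 adjusted over the list alone; median -0.98), with the thymidylate synthase TYMS at -2.15 ± 0.18, thymidine kinase TK1 at -2.00 ± 0.16, the flap endonuclease FEN1 at -1.97 ± 0.17 and PCNA, the clamp of DNA polymerase, at -1.39 ± 0.16. GINS1 fell on 1 of its 2 probe sets (-2.39 ± 0.21) and rose on the other. In the mitosis list 33 of 51 genes fell and 1 rose (34 and 1 adjusted over the list alone; median -0.59), with the centromere genes CENPI at -1.12 ± 0.11 and CENPK at -1.23 ± 0.15, SKA3 at -1.84 ± 0.20 and CDCA3 at -1.35 ± 0.15. CDK1, the mitotic kinase, fell from 4659 ± 784 to 2379.9 ± 229 (-0.95 ± 0.13). Camera with a preset correlation called these 3 lists (adjusted p = 5.52e-15, 5.38e-11 and 2.23e-07); adjusted p = 0.223, 0.177 and 0.280 with an estimated correlation.

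Growth factor response genes and heat shock proteins also fell. In the immediate early list 17 of 28 genes fell and 1 rose (18 and 2 adjusted over the list alone; median -0.89), among them ID2 (-4.04 ± 0.16), EGR1 (-1.98 ± 0.15) and, on 1 of 2 probe sets, ETV4 (-2.37 ± 0.17; the other rose). MYC fell from 1229 ± 317 to 392 ± 67.0 (-1.59 ± 0.20). Of 24 cytosolic heat shock genes, 18 fell and 0 rose (20 and 1 adjusted over the list alone; median -0.89). The chaperone HSPA8 went from 9882 ± 1384 to 2324 ± 144 (-2.07 ± 0.12), and CHORDC1, HSPB8 and HSP90AB1 fell with it (-2.35, -2.52 and -1.82). ANKRD1 (-4.11 ± 0.62; -4.86 without contact-inhibited replicate 1, which had 482 against 38.8 to 52.6 in the others) and the contractile genes ACTG2 (-3.23 ± 0.15), ACTA2 (-1.76 ± 0.19), MYL9 (-1.38 ± 0.08) and TAGLN (-1.25 ± 0.09) fell in the YAP target list, in which 11 of 25 fell and 4 rose (11 and 4 adjusted over the list alone; median -0.34). These 3 lists had adjusted p = 1.36e-05, 1.2e-08 and 0.0220; adjusted p = 0.156, 0.156 and 0.292 with an estimated correlation. The YAP call was lost without cycling replicate 2 (adjusted p = 0.0531) and with quantile normalization (adjusted p = 0.0547).

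Metabolic and secretory genes fell in part. Of 30 genes of the amino acid deprivation response, 14 fell, such as the mitochondrial folate enzyme MTHFD2 (-2.45 ± 0.15), the threonyl-tRNA synthetase TARS (-1.08 ± 0.13) and the cationic amino acid transporter SLC7A3 (-2.18 ± 0.13, with 4 of 7 probe sets lower and 1 higher). In the same list 4 rose, STC2 by 1.30 ± 0.17. Of 22 cholesterol genes 9 fell, with ACAT2 at -1.5 ± 0.18, FDPS at -1.35 ± 0.16 and LBR at -0.99 ± 0.12, and 1 rose, INSIG1, a brake on the pathway (1.2 ± 0.14). Of 22 endoplasmic reticulum chaperone genes 10 fell (HYOU1 -1.15 ± 0.12, HSPA5 -0.77 ± 0.11, XBP1 -0.93 ± 0.13, HSP90B1 -0.69 ± 0.12) and 2 rose. Of 48 respiratory chain genes 19 fell (CYCS -1.60 ± 0.14, NDUFA5 -1.69 ± 0.16, NDUFA4 -0.74 ± 0.08, NDUFA12 -0.61 ± 0.08) and 4 rose. In these 4 lists, adjusted over the list alone, 15, 9, 10 and 19 genes fell and 4, 1, 2 and 4 rose. The medians were -0.39, -0.34, -0.44 and -0.19 (adjusted p = 0.00865, 0.0116, 0.0276 and 0.00805; adjusted p = 0.364, 0.280, 0.318 and 0.412 with an estimated correlation). The cholesterol call was lost without cycling replicate 3 (adjusted p = 0.0509), the chaperone call without contact-inhibited replicate 1 or cycling replicate 2 (adjusted p = 0.0576 and 0.0560), and the chaperone and respiratory chain calls with quantile normalization (adjusted p = 0.0767 and 0.0870).

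Matrix, lysosome and hypoxia genes rose in contact-inhibited cells. The collagen VI genes COL6A1, COL6A2 and COL6A3 rose by 2.11 ± 0.07, 2.19 ± 0.09 and 2.06 ± 0.15, COL6A1 from 2576 ± 140.3 to 11211 ± 617. In the matrix list as a whole 20 of 48 rose and 7 fell (22 and 7 adjusted over the list alone; median 0.43), and MGP was among those that fell. COL1A1 stood at 15107 ± 920.1 and 16980.2 ± 3031 and did not pass (0.15 ± 0.11, limma adjusted p = 0.313). Of 46 autophagy and lysosome genes 23 rose, with the cathepsin CTSB at 1.19 ± 0.10, ATG13 at 1.16 ± 0.11, the mannosidase MANBA at 1.31 ± 0.13 and LAMP1 at 0.74 ± 0.10, and 2 fell (27 and 3 adjusted over the list alone; median 0.46). Of 32 hypoxia genes 17 rose and 2 fell (19 and 3 adjusted over the list alone; median 0.56). The genes that rose included the prolyl hydroxylase P4HA1 (1.33 ± 0.09), NDRG1 (1.33 ± 0.13), BNIP3 (1.35 ± 0.13) and VEGFA (1.34 ± 0.24). In the lipid carrier list 8 of 14 rose and 2 fell (8 and 2 adjusted over the list alone; median 0.47), clusterin, CLU, among the first (2.43 ± 0.19) and apolipoprotein APOA1 among the second (-2.01 ± 0.16). These 4 lists had adjusted p = 0.000794, 9.36e-05, 0.000143 and 0.0116; adjusted p = 0.317, 0.156, 0.156 and 0.156 with an estimated correlation. The lipid carrier call was lost with the mean of all probe sets per gene (adjusted p = 0.0620).

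Genes of the list of cyclin-dependent kinase inhibitors and growth arrest moved apart. CDKN1B (p27) rose from 1666 ± 185 to 3073 ± 151 (0.88 ± 0.12) and CDKN2A by 0.61 ± 0.08, whereas CDKN2B (p15) fell from 1827 ± 107 to 193 ± 12.4 (-3.14 ± 0.09) and RBL1 fell with it (-1.51 ± 0.19). CDKN1A (p21) stood at 2136 ± 301 and 2697 ± 1144 and did not pass (0.26 ± 0.22), with 4405 in contact-inhibited replicate 1. In this list 12 of 23 rose and 4 fell (12 and 5 adjusted over the list alone; median 0.41; adjusted p = 0.0484; adjusted p = 0.304 with an estimated correlation). The call was lost without contact-inhibited replicate 2 (adjusted p = 0.0508), cycling replicate 1 (0.0932) or cycling replicate 2 (0.0511), and with a filter at the median (0.0596) or eBayes without trend (0.0691). CEBPB (-0.36 ± 0.20), CCND1 (-0.28 ± 0.11) and SCD (-0.13 ± 0.17), named in advance, did not pass; without contact-inhibited replicate 1 CEBPB passed (limma adjusted p = 0.00189), and without cycling replicate 3 CCND1 passed (limma adjusted p = 0.0293). Both passed with array weights (0.00336 and 0.00381), CCND1 also with centred arrays (0.00954) and a filter at the median (0.04997), and CEBPB with the W-linked covariate (0.0481).

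Over 28270 probe sets, 5318 were higher and 4513 lower in contact-inhibited than in cycling cells, 1593 and 1474 of them by at least 2-fold. Of the calls 54.1% were higher; this share was 41.6% when each array was centred on its median and 49.6% with quantile normalization. Centring moved the median change of all probe sets from 0.07 to -0.05.

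**Figure D3:**
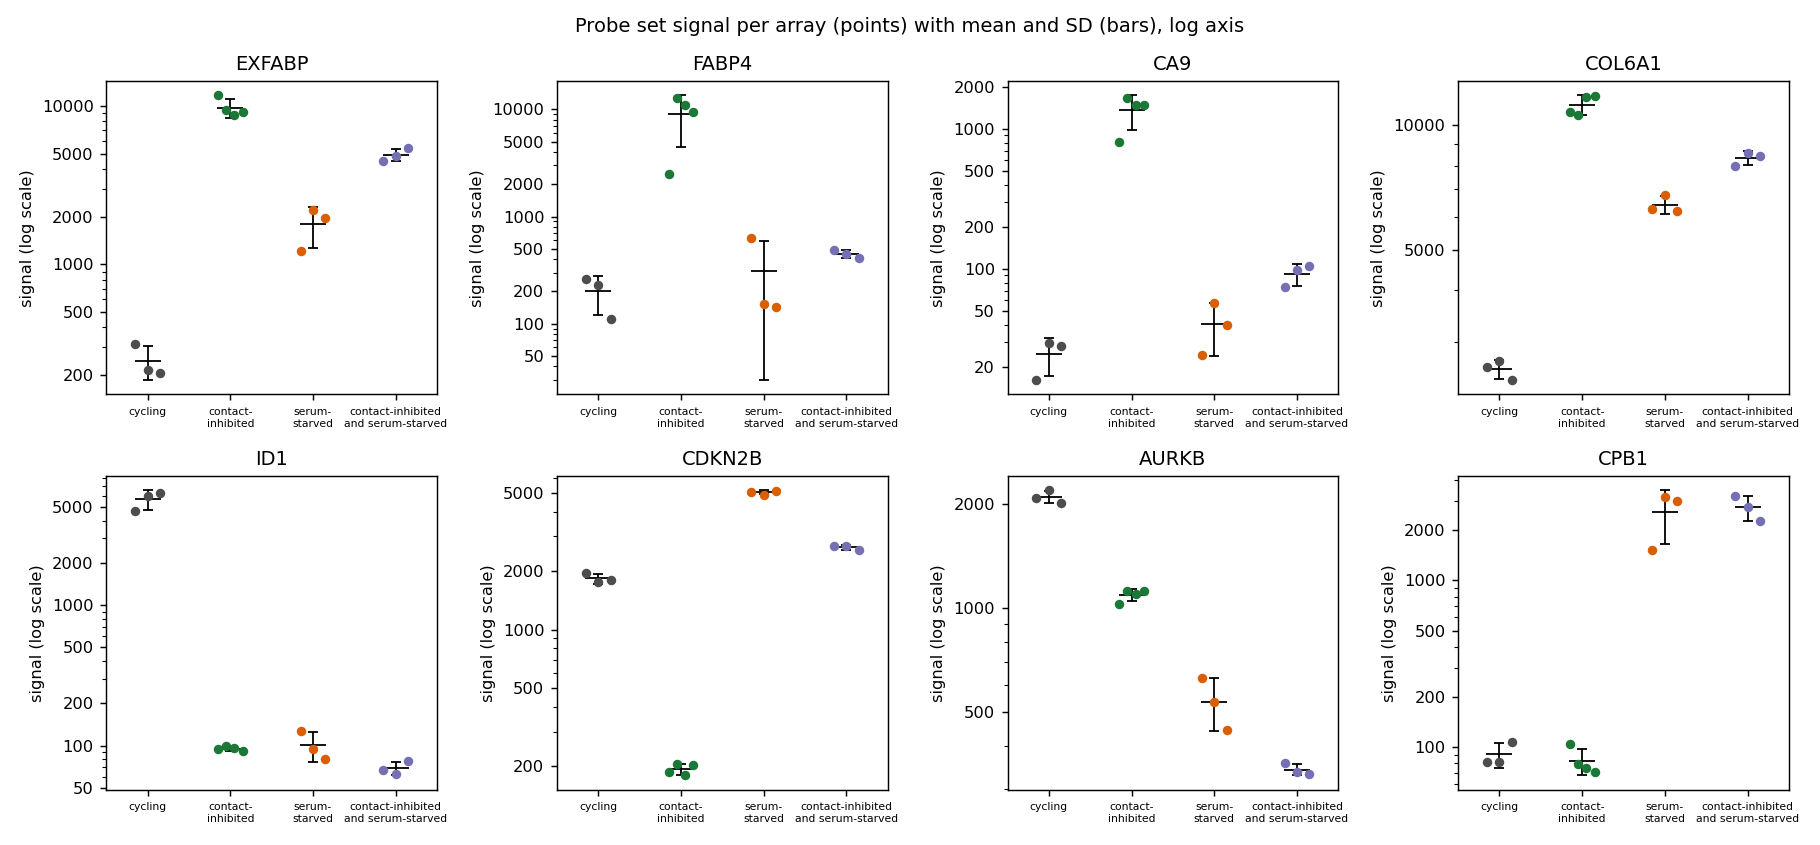
Signal of 8 genes (log axis) for each array, as points by group, with the group mean and SD as bars. EXFABP was at 244, 9732, 1782 and 4921 in the 4 groups from left to right, and CDKN2B at 1827, 193, 5041 and 2636.

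FAM180A and CPB1 rose most in serum-starved cells. FAM180A rose from 20 ± 3.83 to 1846 ± 338 (5.68 ± 0.16). Carboxypeptidase B, CPB1, rose from 90.1 ± 15.0 to 2569.8 ± 905 (4.54 ± 0.25; limma adjusted p = 9.96e-08), its relative CPXM2 by 4.08 ± 0.40, and GATD3AL2 by 4.30 ± 0.32. The matricellular SMOC1 and SPON2 rose by 3.72 ± 0.53 and 3.48 ± 0.35, the metalloproteinase inhibitor TIMP4 by 3.56 ± 0.45 on 1 of 2 probe sets (2.93 without cycling replicate 3), and GAS2, a growth arrest gene that acts on microfilaments, from 329.7 ± 10.8 to 3868 ± 640.4 (3.48 ± 0.37). EXFABP rose to 1782 ± 514, a change of 2.77 ± 0.21.

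As in contact-inhibited cells, DKK4, RGS20 and ID1 were among the lowest (-7.09 ± 0.26, -5.76 ± 0.12 and -5.61 ± 0.17). CRMP1, a mediator of semaphorin signalling, fell from 6124 ± 499.7 to 249 ± 65.1 (-4.56 ± 0.20), and the homeobox gene DLX5 (-4.04 ± 0.29) and the connexin GJC3 (-3.90 ± 0.18) fell too. Cardiac actin, ACTC1, had the highest signal of each cycling array and fell from 61524 ± 19438 to 1363 ± 183 (-5.43 ± 0.63). HINTW, at -5.84 ± 1.11, was also among the lowest, which is the W-linked difference given above (-7.40, -5.001 and -5.13 without serum-starved replicates 1, 2 and 3). ACTC1 moved with it between the confluent arrays: its signal was 989 in contact-inhibited replicate 1 and 7447 to 9907 in replicates 2 to 4.

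Mitosis genes fell in serum-starved cells. Of 51 genes, 43 fell and 0 rose (48 and 0 adjusted over the list alone), with a median of -1.24 (adjusted p = 1.87e-34; adjusted p = 0.0761 with an estimated correlation). The kinase AURKB went from 2093 ± 87.6 to 536 ± 92.3 (-1.95 ± 0.13), the activator of the anaphase-promoting complex CDC20 from 2052 ± 306 to 450.3 ± 92.5 (-2.16 ± 0.16), and the spindle factor TPX2 (-1.72 ± 0.12) and the kinesin KIF2C (-1.49 ± 0.12) fell too. CDK1 fell from 4659 ± 784 to 1748 ± 199.9 (-1.40 ± 0.14). Of 45 replication genes 17 fell and 0 rose (22 and 0 adjusted over the list alone; median -0.43), with the primase subunit PRIM2 at -1.90 ± 0.22, RFC3 at -1.63 ± 0.23, TK1 at -1.41 ± 0.17 and RPA2 at -0.90 ± 0.12. PCNA passed narrowly (-0.57 ± 0.18; limma adjusted p = 0.0417) and did not pass without cycling replicate 1 or 2 or without any one of the 3 serum-starved arrays (limma adjusted p from 0.0512 to 0.141), nor with the compared arrays alone (0.0993) or eBayes without trend (0.0510). Of 46 ribosome biogenesis genes 16 fell and 0 rose (21 and 0 adjusted over the list alone; median -0.40), with NHP2 at -1.45 ± 0.19, NIP7 at -1.04 ± 0.15, IMP4 at -0.97 ± 0.19 and EBNA1BP2 at -0.67 ± 0.12. The last 2 lists had adjusted p = 1.29e-07 and 3.37e-08; adjusted p = 0.230 and 0.292 with an estimated correlation. With the W-linked level as a covariate, chosen after seeing the data, the ribosome list had a median of -0.12 (adjusted p = 0.146), and PCNA (-0.31 ± 0.24) and EBNA1BP2 (-0.54 ± 0.17) did not pass (limma adjusted p = 0.455 and 0.0625).

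Sterol, respiratory chain and heat shock genes fell in smaller numbers. Of 22 cholesterol genes 11 fell and 0 rose, with FDPS at -1.30 ± 0.17, NSDHL at -1.31 ± 0.26, DHCR7 at -0.77 ± 0.14 and MSMO1 at -0.42 ± 0.07. Of 48 respiratory chain genes 15 fell and 0 rose, with cytochrome c, CYCS, at -1.07 ± 0.15, NDUFA8 at -0.69 ± 0.13, ATP5G1 at -0.68 ± 0.11 and NDUFA2 at -0.58 ± 0.10. Of 24 heat shock genes 8 fell and 0 rose, with HSPB9 at -2.61 ± 0.23, CHORDC1 at -1.60 ± 0.13, HSPB8 at -1.25 ± 0.15 and AHSA1 at -0.87 ± 0.14. Of 16 skeletal muscle markers 4 fell, namely ACTC1, MYL4 (-3.51 ± 0.14), ACTA1 (-1.61 ± 0.32) and TNNC1 (-1.1 ± 0.19), and 1 rose. Adjusted over the list alone, 12, 19, 9 and 4 fell and 0, 0, 0 and 1 rose in these 4 lists. The medians were -0.44, -0.26, -0.36 and -0.12 (adjusted p = 1.98e-05, 1.18e-06, 3.68e-05 and 0.0382; adjusted p = 0.167, 0.230, 0.167 and 0.167 with an estimated correlation). The muscle call was lost without cycling replicate 1 (adjusted p = 0.117), without serum-starved replicate 1 (0.0899) and with an offset of 1 (0.0617). NSDHL, DHCR7 and NDUFA8 did not pass with the W-linked covariate, at -0.50 ± 0.23, -0.45 ± 0.17 and -0.61 ± 0.18 (limma adjusted p = 0.191, 0.111 and 0.0521).

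The matrix, protease, amino acid deprivation and lysosome lists passed as higher in serum-starved cells. Fibulin FBLN5 went from 41.1 ± 6.90 to 626 ± 162 (3.46 ± 0.30), fibrillin FBN2 rose by 2.61 ± 0.22, and COL6A1 and COL6A2 by 1.31 ± 0.07 and 1.5 ± 0.10, in a list in which 20 of 48 rose and 2 fell (median 0.44). Cathepsin CTSV (1.74 ± 0.15) and the gelatinase MMP2 (1.31 ± 0.12) rose in the protease list, where 7 of 31 rose and 1 fell, SERPINB2 (-2.61 ± 0.36; median of the list 0.32). Of 30 amino acid deprivation genes 12 rose and 1 fell (median 0.28), with CHAC1, an enzyme of glutathione breakdown, at 1.88 ± 0.27, CTH at 1.57 ± 0.23 and the serine synthesis enzyme PHGDH at 1.12 ± 0.20. Of 46 lysosome genes 15 rose and 0 fell (median 0.33), with ATG13 at 1.2 ± 0.12, MANBA at 1.18 ± 0.14, HEXA at 0.95 ± 0.15 and the autophagosome marker MAP1LC3B at 0.73 ± 0.11. Adjusted over the list alone, 23, 10, 14 and 15 rose and 3, 1, 3 and 1 fell in these 4 lists (adjusted p = 5.60e-07, 0.0130, 0.0144 and 0.000205; adjusted p = 0.199, 0.230, 0.512 and 0.167 with an estimated correlation). The amino acid call was lost without serum-starved replicate 1 (adjusted p = 0.0872), and the protease and lysosome calls with the W-linked level as a covariate (medians 0.09 and 0.22; adjusted p = 0.246 and 0.128).

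In the list of cyclin-dependent kinase inhibitors and growth arrest, CDKN2A and CDKN2B were both higher in serum-starved cells. CDKN2A rose from 1745 ± 116 to 5458 ± 219.5 (1.64 ± 0.09), CDKN2B from 1827 ± 107 to 5041 ± 113 (1.46 ± 0.10) and CCNG1 by 0.59 ± 0.08. CDKN1A rose by 0.93 ± 0.24 (limma adjusted p = 0.0164) but did not pass without cycling replicate 1 (0.0553), serum-starved replicate 2 (0.0545) or serum-starved replicate 3 (0.0689), and with the W-linked covariate its change was 0.15 ± 0.19 (0.659). CDKN1B did not pass (0.02 ± 0.13) and changed sign without cycling replicate 1, cycling replicate 2 or serum-starved replicate 3 (-0.0013, -0.043 and -0.049). In the list 6 of 23 rose and 2 fell. Of 32 hypoxia genes 12 rose, with P4HA1 at 1.27 ± 0.10, RORA at 1.67 ± 0.16, NDRG1 at 1.42 ± 0.14 and DDIT4 at 0.69 ± 0.10, and 2 fell. Of 14 lipid carriers 5 rose, with CLU at 1.65 ± 0.20 and APOA1 at 1.65 ± 0.18, and 1 fell, FABP7 (-1.79 ± 0.39; -2.39 without serum-starved replicate 1; -1.22 ± 0.55 with the W-linked covariate, limma adjusted p = 0.181, and 0.0636 with the compared arrays alone). When adjusted over the list alone, 6, 12 and 6 rose and 3, 3 and 1 fell in these 3 lists. The medians were 0.20, 0.24 and 0.28 (adjusted p = 0.0220, 0.0209 and 0.0330; adjusted p = 0.230, 0.230 and 0.167 with an estimated correlation). The 3 calls were lost, in the same order, without cycling replicate 1 (0.0536), without cycling replicate 3 (0.0591) and without serum-starved replicate 1 (0.0897), and the first 2 also with the W-linked covariate (medians -0.058 and 0.20; adjusted p = 0.479 and 0.158). The genes named in advance MYC (0.42 ± 0.22), EGR1 (0.30 ± 0.16), CCND1 (0.24 ± 0.11), CEBPB (-0.60 ± 0.21), SCD (-0.46 ± 0.18), VEGFA (0.26 ± 0.26) and COL1A1 (0.10 ± 0.12) did not pass, and VEGFA changed sign without cycling replicate 3 (-0.061). CEBPB passed with centred arrays (limma adjusted p = 0.0329), array weights (0.00174), the compared arrays alone (0.0125) and the W-linked covariate (0.00971), SCD with quantile normalization (0.0487) and EGR1 with the W-linked covariate (0.0238).

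In all, 2866 probe sets were higher and 1847 lower in serum-starved than in cycling cells, 1097 and 496 by at least 2-fold. Without serum-starved replicate 3 the counts were 1518 and 1034, and without replicate 2 the lower count was 1180. With array weights they were 4504 and 3378, and with the compared arrays alone 1803 were higher. Of the calls 60.8% were higher, and 45.4% with each array centred on its median. With the W-linked level as a covariate 1015 were lower.

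FAM180A, CPXM2 and CPB1 rose most in cells that were both confluent and starved. FAM180A rose from 20 ± 3.83 to 2269 ± 86.7 (5.99 ± 0.16), CPXM2 to 1493 ± 701 (5.23 ± 0.40) and CPB1 to 2753 ± 469 (4.70 ± 0.25). The Wnt modulator SFRP2 rose from 103 ± 11.7 to 2421 ± 221 (4.35 ± 0.18), TIMP4 by 4.44 ± 0.45 (3.82 without cycling replicate 3), SMOC1 by 4.37 ± 0.53, COCH by 4.33 ± 0.38, and EXFABP by 4.26 ± 0.21. CUTAL, near 0 in cycling cells, stood at 344 ± 39.8. HINTW, DKK4, ID1 and RGS20 were the lowest (-7.48 ± 1.11, -7.05 ± 0.26, -6.05 ± 0.17 and -5.88 ± 0.12), followed by ACTC1 (-5.43 ± 0.63), MYH15 (-5.10 ± 0.25), CRMP1 (-4.98 ± 0.20) and DLX5 (-4.30 ± 0.29).

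The mitosis list had its lowest median in this group. Of 51 genes 48 fell and 0 rose (48 and 0 adjusted over the list alone; median -1.66). AURKB stood at 342 ± 12.9, CDC20 at 292 ± 24.7 and TPX2 at 553 ± 16.2, changes of -2.56 ± 0.13, -2.74 ± 0.16 and -2.06 ± 0.12, and CENPI fell as well (-1.93 ± 0.12). CDK1 fell from 4659 ± 784 to 1195 ± 62.3 (-1.94 ± 0.14) and PCNA from 2829 ± 676 to 1491 ± 201 (-0.90 ± 0.18). In ribosome biogenesis 33 of 46 fell (NPM3 -1.88 ± 0.20, NHP2 -1.86 ± 0.19, NIP7 -1.33 ± 0.15, NOLC1 -1.28 ± 0.15) and 0 rose. In DNA replication 29 of 45 fell (RFC3 -2.15 ± 0.23, TK1 -1.99 ± 0.17, PRIM2 -1.98 ± 0.22, FEN1 -1.78 ± 0.19) and 0 rose. Adjusted over the list alone, 37 and 29 fell and 0 and 0 rose, with medians of -0.68 and -0.71. The 3 lists had adjusted p = 5.30e-31, 4.46e-11 and 3.60e-10; adjusted p = 0.0668, 0.276 and 0.215 with an estimated correlation.

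Sterol synthesis genes fell in most members. Of 22 cholesterol genes 17 fell and 0 rose (19 and 1 adjusted over the list alone; median -0.70), with NSDHL at -2.03 ± 0.26, FDPS at -1.70 ± 0.17, PMVK at -1.39 ± 0.20 and the squalene epoxidase SQLE at -1.01 ± 0.14. The stearoyl-CoA desaturase gene SCD fell from 178 ± 23.7 to 103 ± 14.6 (-0.70 ± 0.18). Of 48 respiratory chain genes 18 fell and 1 rose (21 and 2 adjusted over the list alone; median -0.26), with CYCS at -1.62 ± 0.15, UQCRHL at -1.02 ± 0.14, ATP5B at -0.91 ± 0.10 and ATP5G3 at -0.90 ± 0.09. Of 24 heat shock genes 10 fell and 2 rose (13 and 2 adjusted over the list alone; median -0.45), with HSPB9 at -2.34 ± 0.23, CHORDC1 at -1.76 ± 0.13, HSP90AB1 at -1.38 ± 0.15 and HSPB8 at -1.34 ± 0.15. The 3 lists had adjusted p = 8.11e-08, 1.23e-05 and 0.000203; adjusted p = 0.0668, 0.279 and 0.215 with an estimated correlation.

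Matrix genes rose in 27 of 48 cases and fell in 2 (29 and 2 adjusted over the list alone; median 0.59), with FBLN5 at 3.76 ± 0.30, FBN2 at 3.41 ± 0.22, COL6A1 at 1.69 ± 0.07 and COL6A2 at 1.67 ± 0.10; COL1A1 did not pass (0.14 ± 0.12). Lysosome genes rose in 22 of 46 cases and fell in 1 (24 and 2 adjusted over the list alone; median 0.47), with the ceramidase ASAH1 at 1.21 ± 0.16, MANBA at 1.15 ± 0.14, HEXA at 1.1 ± 0.15 and MAP1LC3B at 0.98 ± 0.11. Among growth arrest genes 10 of 23 rose and 3 fell (12 and 3 adjusted over the list alone; median 0.53). GAS2 rose by 3.15 ± 0.37, PRRX1 by 1.34 ± 0.20, CDKN2A by 1.26 ± 0.09, CDKN1A by 1.26 ± 0.24, CCNG1 by 0.66 ± 0.08, CDKN1B by 0.65 ± 0.13 and CDKN2B by 0.53 ± 0.10. Among hypoxia genes 13 of 32 rose, with NDRG1 at 1.91 ± 0.14, RORA at 1.45 ± 0.16 and P4HA1 at 1.31 ± 0.10, and 3 fell, among them STC2 (-1.60 ± 0.18; 15 and 3 adjusted over the list alone; median 0.27). The 4 lists had adjusted p = 8.08e-07, 9.09e-05, 0.00333 and 0.0342; adjusted p = 0.215, 0.215, 0.215 and 0.276 with an estimated correlation. The growth arrest and hypoxia calls were lost with the W-linked covariate (medians 0.29 and 0.29; adjusted p = 0.152 and 0.169). CDKN1A, CDKN1B, PRRX1 and PCNA did not pass with it either, at 0.39 ± 0.20, 0.49 ± 0.19, 0.73 ± 0.24 and -0.61 ± 0.26 (limma adjusted p = 0.206, 0.0980, 0.0542 and 0.121). The hypoxia call was also lost without cycling replicate 3 (0.0797), without confluent and starved replicate 3 (0.0513), with array weights (0.106) and with a filter at the median (0.0764). MYC (0.33 ± 0.22), EGR1 (0.41 ± 0.16), CCND1 (0.28 ± 0.11), CEBPB (-0.18 ± 0.21) and VEGFA (0.29 ± 0.26) did not pass, and VEGFA changed sign without cycling replicate 3 (-0.036). CCND1 passed without confluent and starved replicate 1 (limma adjusted p = 0.0407). EGR1 passed with quantile normalization (0.0428), array weights (0.0260), the compared arrays alone (0.0498) and the W-linked covariate (0.00913), and COL1A1 with array weights (0.0497).

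Against cycling cells, 4959 probe sets were higher and 3431 lower in confluent and starved cells, 1902 and 952 of them by at least 2-fold. Of the calls 59.1% were higher, 48.8% with each array centred on its median and 49.1% with quantile normalization. With the W-linked level as a covariate the counts were 3174 and 1656, and with array weights 5537 were lower.

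**Figure D4:**
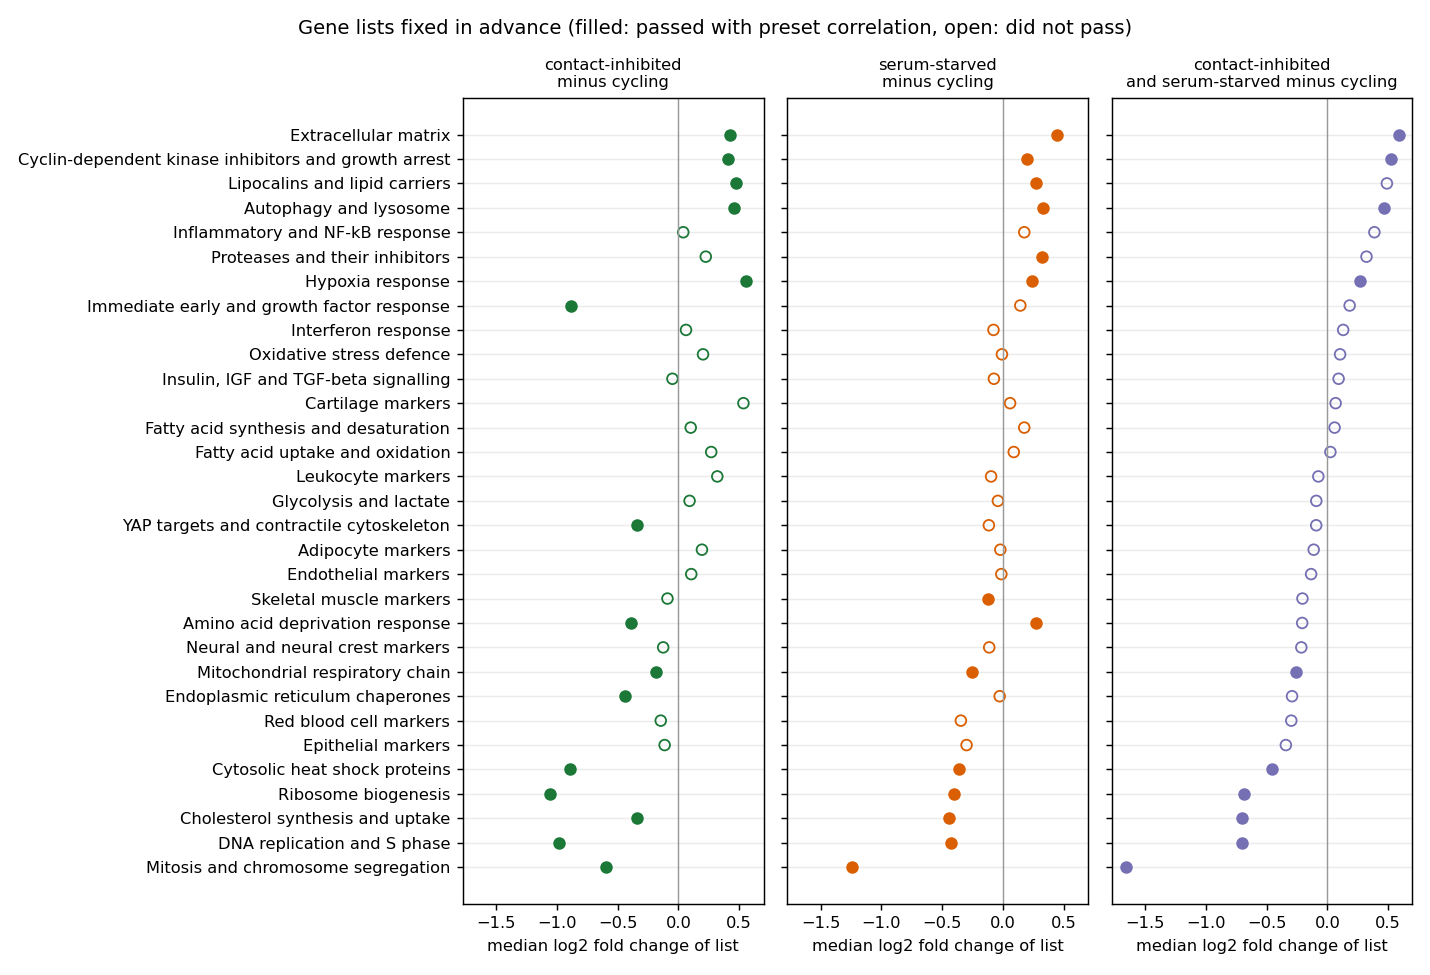
Median log2 fold change of 31 gene lists (vertical axis) in each arrested group against cycling cells (panels), with filled points for lists that passed camera with a preset correlation and open points for those that did not. The mitosis list stands at -0.59, -1.24 and -1.66, and the immediate early list at -0.89, 0.14 and 0.18.

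The remaining lists did not pass in any comparison against cycling cells. In contact-inhibited, serum-starved and doubly arrested cells in turn, 11, 10 and 13 of 33 inflammatory genes rose and 6, 3 and 5 fell. For 34 interferon genes these counts were 7, 3 and 7 against 8, 3 and 3; for 36 oxidative stress genes 10, 6 and 11 against 8, 2 and 7. Glycolysis (20 genes) gave 7, 4 and 4 against 4, 2 and 5, fatty acid synthesis (23) 6, 1 and 3 against 6, 2 and 6, and fatty acid uptake and oxidation (26) 9, 2 and 3 against 2, 3 and 2. Insulin, IGF and TGF-beta signalling (32) gave 8, 7 and 11 against 6, 10 and 9. Among markers of other cell types, 7, 3 and 3 of 12 cartilage genes rose and 2, 3 and 3 fell. For adipocytes (14) the counts were 4, 0 and 0 against 0, 2 and 1, for leukocytes (14) 6, 0 and 0 against 1, 0 and 1, and for endothelium (16) 2, 3 and 3 against 5, 2 and 3. For epithelium (12) they were 0, 0 and 1 against 3, 3 and 3, for neural cells (18) 1, 1 and 1 against 4, 2 and 4, and for red blood cells (9) 0, 1 and 1 against 2, 2 and 4. The immediate early list, called in contact-inhibited cells, had medians of 0.14 and 0.18 in the starved groups, where its mean and its test pointed down (adjusted p = 0.924 and 0.816). Median and mean also differed in sign for the cartilage list in both starved groups and for the endothelial and interferon lists in contact-inhibited cells. The same held in serum-starved cells for fatty acid uptake, glycolysis, endoplasmic reticulum chaperones and oxidative stress, in the doubly arrested cells for fatty acid synthesis, and in the interaction for the inflammatory, oxidative stress and endothelial lists.

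Starved cells and contact-inhibited cells were compared directly as well. Serum-starved cells exceeded contact-inhibited cells in CDKN2B (5041 ± 113 against 193 ± 12.4; 4.60 ± 0.09), MXRA5 (4.97 ± 0.34), CPB1 (4.66 ± 0.23), FBLN5 (4.43 ± 0.28) and MGP (4.21 ± 0.37). They were lower in FABP4 (-4.88 ± 0.56), CA9 (-4.60 ± 0.26), the retinol-binding RBP7 (-4.58 ± 0.71), PROK2 (-4.49 ± 0.18) and the coagulation factor subunit F13A1 (-3.88 ± 0.55). In total 3343 probe sets were higher and 2119 lower, and 1333 were lower without serum-starved replicate 2. With array weights the counts were 5070 and 3938, and 3391 were lower with cycling replicate 3 and contact-inhibited replicate 1 both removed, chosen after seeing the data. FABP4 was at -5.54 without serum-starved replicate 1. Adding starvation to confluence gave higher CCK, a peptide hormone (4446 ± 505 against 124 ± 160.3; 5.56 ± 0.54), CYP24A1, the vitamin D hydroxylase (5.07 ± 0.70), CPB1 (4.82 ± 0.23), FBLN5 (4.73 ± 0.28) and CPXM2 (4.32 ± 0.37). It gave lower HINTW (-5.33 ± 1.04), OSTN (-5.21 ± 0.54), RBP7 (-4.59 ± 0.71), FABP4 (-4.05 ± 0.56) and, on 1 of 3 probe sets, ADAMTSL3 (-4.15 ± 0.72; 1 other went up). Contact-inhibited replicate 1, low in W-linked transcripts, had 364 for CCK, 141 for CYP24A1, 642 for RBP7 and 622 for F13A1, and differed from the other contact-inhibited arrays in each. Without it serum-starved cells stood at -5.52 for RBP7 and -4.60 for F13A1, and doubly arrested cells at 6.23 for CCK, 5.85 for CYP24A1, -6.23 for HINTW, -5.94 for OSTN and -5.53 for RBP7. With the W-linked covariate the serum-starved values were -2.99 ± 0.33 for FABP4, -2.18 ± 0.42 for RBP7 and -2.33 ± 0.52 for F13A1, and the doubly arrested values 3.41 ± 0.27 for CCK, 2.23 ± 0.28 for CYP24A1, -3.27 ± 0.45 for OSTN, -1.88 ± 0.45 for RBP7 and -1.91 ± 0.35 for FABP4, and HINTW (-1.24 ± 0.57) and ADAMTSL3 (-1.97 ± 0.78) did not pass (limma adjusted p = 0.168 and 0.110). In this comparison 3005 probe sets were higher and 1862 lower; without any one confluent and starved array the lower count was 1110 to 1234, and without replicate 2 of that group the higher count was 1958. With array weights the counts were 6006 and 4139, and with both arrays removed 2890 were lower.

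Adding confluence to starvation gave 137 probe sets higher and 135 lower, and 3681 had an unadjusted p under the threshold of 0.05. K123 (591 ± 116 against 93.7 ± 5.83; 2.45 ± 0.41), CUTAL (2.42 ± 0.46), ADAMTSL1 (2.04 ± 0.18), fibrinogen FGA (1.97 ± 0.36) and the small GTPase GEM (1.79 ± 0.24) were highest. On 1 of 5 probe sets the ribosomal protein gene RPS13 (146 ± 2.86 against 773 ± 68.7; -2.28 ± 0.15), together with NCF4 (-2.17 ± 0.31), GNAZ (-2.27 ± 0.35), NELL2 (-2.13 ± 0.39) and TAF4B (-2.36 ± 0.47) were lowest. The higher and lower counts were 41 and 44, 10 and 21, and 26 and 49 without confluent and starved replicates 1, 2 and 3, and 35 and 40, 38 and 49, and 79 and 75 without serum-starved replicates 1, 2 and 3. They were 41 and 54 with a replicate block, but 315 and 281 with the W-linked covariate, 433 and 430 with the compared arrays alone, 1101 and 918 with cycling replicate 3 and contact-inhibited replicate 1 removed, and 2124 and 1571 with array weights, so the size of this difference rests on the fit. NELL2 was at -1.5 without serum-starved replicate 1. CUTAL and TAF4B did not pass without any one of these 6 arrays (limma adjusted p from 0.0515 to 0.151), nor FGA and NELL2 without any one confluent and starved array (0.0740 to 0.119). K123 did not pass without confluent and starved replicates 2 or 3 or serum-starved replicates 1 or 2 (0.0563 to 0.0857), and GNAZ without confluent and starved replicates 2 or 3 or serum-starved replicate 1 (0.0501 to 0.0664). Of the calls 50.4% were higher, 36.8% with quantile normalization.

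How confluence and starvation combined was tested by their interaction, the effect of starvation in confluent cells minus that in sparse cells. It was positive for DKK4 (6.44 ± 0.36), RGS20 (5.65 ± 0.16) and ID1 (5.22 ± 0.23), which either condition alone had brought to low signal, and for SERPINB2 (5.78 ± 0.50) and ANKRD1 (5.13 ± 0.91). It was negative for FAM180A (-5.82 ± 0.22), at 2528, 1846 and 2269 in the 3 arrested groups, and for OSTN (-5.37 ± 0.80), SPON2 (-5.08 ± 0.48), NELL2 (-4.41 ± 0.53) and FABP4 (-4.39 ± 0.82). FABP4 and CA9 (-4.08 ± 0.38) were high in contact-inhibited cells with serum and stood at 447 ± 36.3 and 92.1 ± 16 without it. Of 28270 probe sets, 1686 had a positive and 1371 a negative interaction. The share of positive calls was 55.2%, and 69.7% with each array centred on its median. Without confluent and starved replicate 1 the counts were 1074 and 856, without replicate 2 of that group 1074 and 877, without serum-starved replicate 2 1102 and 889, and without serum-starved replicate 3 1079 and 829. With array weights they were 3901 and 3237, and with cycling replicate 3 and contact-inhibited replicate 1 removed 2602 and 2227. Without contact-inhibited replicate 1 ANKRD1 was at 5.88 and OSTN at -6.10, and without serum-starved replicate 1 NELL2 was at -3.78 and FABP4 at -3.72.

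Among the lists, growth genes had a positive interaction: 22 of 46 ribosome biogenesis genes (median 0.78, POLR1E 1.12 ± 0.20), 14 of 24 heat shock genes (0.83, HSPA8 1.65 ± 0.18), 18 of 45 replication genes (0.67, SLBP 1.51 ± 0.26), 12 of 28 immediate early genes (0.65, DUSP6 1.48 ± 0.18) and 9 of 25 YAP targets (0.41, ACTG2 2.99 ± 0.21), with none negative. EGR1 (2.09 ± 0.21) and MYC were such genes: with serum, confluence brought MYC to 392 ± 67.0, and without serum confluent cells held 1521 ± 115 (1.51 ± 0.30). Adjusted over the list alone, 33, 18, 27, 12 and 9 were positive and 0, 0, 0, 1 and 2 negative (adjusted p = 7.88e-12, 1.02e-09, 1.14e-08, 9.95e-07 and 0.00360; adjusted p = 0.248, 0.0844, 0.196, 0.116 and 0.196 with an estimated correlation). Hypoxia genes were negative in 11 of 32 cases and positive in 2 (-0.53, ERO1A -1.71 ± 0.26), matrix genes in 10 of 48 and 5 (-0.35), lysosome genes in 6 of 46 and 0 (-0.31), lipid carriers in 6 of 14 and 1 (-0.81) and glycolysis genes in 4 of 20 and 1 (-0.17, ENO2 -2.67 ± 0.47). Adjusted over the list alone, 16, 15, 11, 7 and 8 were negative and 3, 8, 0, 1 and 1 positive (adjusted p = 1.47e-05, 0.00358, 0.000694, 0.00360 and 0.0144; adjusted p = 0.0844, 0.376, 0.181, 0.0844 and 0.259 with an estimated correlation).

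The mitosis, respiratory chain, protease, cartilage, leukocyte and adipocyte lists also passed (adjusted p = 0.0428, 0.0144, 0.0192, 0.0248, 0.0420 and 0.0483; adjusted p = 0.575, 0.539, 0.259, 0.151, 0.259 and 0.181 with an estimated correlation), and each of these 6 calls was lost with quantile normalization (adjusted p from 0.0513 to 0.373). Mitosis genes were positive in 6 of 51 cases (BUB3 0.64 ± 0.14). The mitosis call was lost without confluent and starved replicates 1 or 2, contact-inhibited replicates 1 or 3, cycling replicate 2 or serum-starved replicates 2 or 3 (adjusted p from 0.0514 to 0.148). The leukocyte call was lost without confluent and starved replicates 1 or 2, contact-inhibited replicates 1 or 3, cycling replicates 2 or 3 or serum-starved replicate 1 (0.0514 to 0.0786). The adipocyte call was lost without confluent and starved replicates 1 or 2, contact-inhibited replicates 2, 3 or 4, cycling replicates 1 or 2 or serum-starved replicates 2 or 3 (0.0505 to 0.0754). The respiratory chain call was lost without cycling replicate 3 (0.0550) or serum-starved replicate 3 (0.0649), and the protease call without contact-inhibited replicate 1 (0.0619).

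The 2 estimates of each factor, taken from arrays that they do not share, were set against each other over all tested probe sets, which are not independent replicates. The effect of confluence with serum and that without serum correlated at r = 0.382 across probe sets (jackknife SE of r over arrays 0.0697; Spearman rho = 0.392). Of the probe sets higher with confluence, 94 were called in both settings, where independent lists would share 25.8, and of those lower 89, where they would share 21.6; 32 were called in opposite directions (47.3 for independent lists). The effect of starvation in sparse and in confluent cells correlated at r = 0.325 (jackknife SE 0.0413; rho = 0.227), with 886 probe sets higher in both (305 for independent lists), 416 lower in both (122) and 318 in opposite directions (385). Against the shared cycling arrays, the changes of contact-inhibited and serum-starved cells correlated at r = 0.634, with 0.533 in simulated unchanged groups and a covariance of 0.226 against 0.0232 simulated. The changes of contact-inhibited and of doubly arrested cells correlated at r = 0.690 (0.534 simulated, covariance 0.301 against 0.0232), and those of serum-starved and doubly arrested cells at r = 0.896 (0.502 simulated, covariance 0.316 against 0.0233). The simulation gave all arrays the same spread, independent between probe sets, whereas cycling replicate 3 stood apart from its group. The simulated values may therefore understate what the shared cycling arrays contribute.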

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

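The tests on W-linked transcripts, on the culture of origin and on RNA length were chosen only after the result was seen. The splits of the arrays and the test of proliferation were set before, but the rule that decides the latter was set again after its values were seen. Among 90 named genes examined in the 4 contact-inhibited arrays, 16 had 1 array far from the other 3, where chance gives about 1 in 20. In replicate 1 these were CA9 at 811, PROK2 at 663, OSTN at 659, CDKN1A at 4405, ACAT2 at 552, NDRG1 at 3641, NOLC1 at 181, HSP90B1 at 3921, MXRA5 at 11.4, FBLN5 at 37.9, RBP7 at 642, F13A1 at 622, CCK at 364, CYP24A1 at 141 and HINTW at 84.3. In replicate 3 it was CENPI at 203.

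HINTW and the mean of the W-linked probe sets were low in contact-inhibited replicate 1 and in the starved arrays. Replicate 1 had serum per its label, yet held HINTW at a ratio of 0.0685 to the mean of replicates 2 to 4. The mean log2 level of its W-linked probe sets was 6.28 against 7.19 to 7.30. If the label holds, serum removal does not account for the low HINTW of this 1 array. The median ratio over the W-linked genes, 0.749, did not meet the rule first written for this test. That rule was set again, on HINTW and the probe set mean, after these values were seen. In the starved arrays serum removal stays open. The values argue against replicate 1 being a mislabelled doubly arrested array. Over 1425 probe sets its median position was 0.222 between the other contact-inhibited arrays at 0 and the starved mean at 1. The bootstrap interval, 0.192 to 0.256, measures the spread between probe sets of 1 array and not between arrays. By the same rule replicates 2, 3 and 4 lay at 0.012, -0.030 and 0.050. A difference in the sex of the source embryos may underlie the pattern and cannot be told apart from serum removal. Z-linked levels relative to autosomes were 0.015 to 0.068 log2 in the 6 starved and -0.090 to -0.014 in the 7 unstarved arrays. Replicate 1, the only unstarved array with low W-linked levels, had -0.054. These differences are small: the median shift of replicate 1 from replicates 2 to 4 varied between autosomes with an SD of 0.048. By the rule written for this test replicate 1 counts against a difference in sex, but that rests on 1 array. Whether the culture of origin rather than serum removal accounts for calls between confluent cells with and without serum cannot be told apart either. Replicate 1 lay beyond the midpoint toward the starved mean at 28.6% of probe sets, and it is the only array that separates origin from serum. The rule written for this test took a minority of probe sets beyond the midpoint as against the culture of origin. That rule was not applied, since 1 array cannot decide the question.

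Cycling replicate 3 stood apart from the other cycling arrays. Its ratio of 3 prime to 5 prime signal was the highest of 13 arrays for 3 of 3 control genes. The next highest was close for GAPDH (1.33 against 1.22 in doubly arrested replicate 3) and EF1A (1.41 against 1.37 in contact-inhibited replicate 1). Less intact RNA or a shorter labelled product may account for it, although this was found and tested on the same array. The labels give every array an RNA integrity number of at least 9.7. Another state of proliferation cannot be told apart from these. The median over the mitosis list was -0.036 against the mean of replicates 1 and 2, within the bound set before the test. By that bound alone the test spoke against another state of proliferation. A condition on the quartiles was added after the values were seen, since the bound decides nothing where the genes go both ways. Of the mitosis genes 22 were higher and 29 lower, with quartiles of -0.305 and 0.140. No biological explanation given by the design applies to 1 array of a group.

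The interaction of confluence and starvation passed for 1686 positive and 1371 negative probe sets. Of 100 regroupings of the arrays, 1, the real one, called as many as 3057, a share under 0.05, but the highest other regrouping called 3050. The real count thus stands barely above that of another grouping. The regroupings moved arrays among all 4 groups, so other differences between the groups can appear in them as an interaction. These counts therefore decide nothing about chance for the interaction. Of 171 named genes 118 passed, against 10.8% of all tested probe sets. The named genes were in large part picked from these data for large changes or for the interaction, so a high share was built in. The interaction values that follow are on the log2 scale. Ribosome biogenesis genes had NOLC1 1.34, NOP16 1.42, EBNA1BP2 1.04, NHP2 1.46, NIP7 1.12, NPM3 1.07 and POLR1E 1.12. For DNA replication genes it was PCNA 1.06, TK1 1.42, TYMS 1.96, GINS1 1.74, FEN1 1.34, PRIM2 1.57, RPA2 1.07, RFC3 1.09 and SLBP 1.51. The mitosis genes gave SKA3 1.39, CENPK 0.79, BUB3 0.64, NCAPG 0.87 and INCENP 0.85. In heat shock genes it stood at CHORDC1 2.19, HSPB8 2.43, HSPA8 1.65, HSP90AB1 0.76, HSPB9 2.87 and AHSA1 1.12. Immediate early genes had ID1 5.22, MYC 1.51, EGR1 2.09, ID2 3.89, ETV4 1.70 and DUSP6 1.48. For YAP target genes it was ACTG2 2.99, MYL9 1.37, TAGLN 1.19, ACTA2 1.72 and ANKRD1 5.13. The hypoxia genes gave CA9 -4.08, VEGFA -1.31, P4HA1 -1.30, NDRG1 -0.84, BNIP3 -1.07, STC2 -2.01, DDIT4 -0.95, ERO1A -1.71 and SLC2A1 -0.67. In matrix genes it stood at MGP 4.11, COL6A1 -1.74, COL6A2 -2.01 and COL6A3 -2.19. Amino acid response genes had MTHFD2 1.55, SLC7A3 0.93 and PHGDH -1.02. For lysosome genes it was ATG13 -1.58, MANBA -1.33, HEXA -0.75 and WIPI1 -1.13. Positive values among further genes were DKK4 6.44, SERPINB2 5.78, RGS20 5.65, CCK 4.93, MYL4 4.66, PKP2 4.49, CYP24A1 4.36, CRMP1 4.00, MYH15 3.62 and COL2A1 3.61. Also positive were ACTC1 3.57, GJC3 3.47, ACTA1 3.38, ADAMTSL1 2.67, APOA1 2.23, CDKN2B 2.21, DLX5 1.94, TNNC1 1.69, NDUFA5 1.31 and CYCS 1.05. Above 0 came further RBL1 0.96, ACAT2 0.95, FDPS 0.95, LBR 0.88, NDUFA8 0.70, HYOU1 0.70, NDUFA4 0.68, LDHB 0.65 and NDUFA12 0.57. Negative values among further genes were FAM180A -5.82, OSTN -5.37, SPON2 -5.08, NELL2 -4.41, FABP4 -4.39, EXFABP -3.74, ACAN -3.53, PROK2 -3.27, TGM2 -3.08 and GATD3AL2 -2.88. Also negative were CA12 -2.87, F13A1 -2.71, ENO2 -2.67, MMP16 -2.27, RPS13 -2.18, COCH -2.02, GEM -1.97, NCF4 -1.78, CLU -1.70 and COMP -1.54. Below 0 came further CTSV -1.5, AGPAT2 -1.36, SLC16A3 -1.26, MMP2 -1.07, INSIG1 -1.05, COL9A1 -1.01, CDKN2A -0.99, PRRX1 -0.97, CTSB -0.85 and LY86 -0.76. The negative side further held LCP1 -0.72. ACAN had mean signals under the filter level of 22.7 in cycling, serum-starved and doubly arrested cells (16.1, 17.0 and 14.9), so its value depends on the offset. Without contact-inhibited replicate 1 ANKRD1 was at 5.88, OSTN at -6.10, CCK at 5.60, CYP24A1 at 5.14, ACTC1 at 2.81 and F13A1 at -3.43. Without serum-starved replicate 1 CYP24A1 was at 3.61, NELL2 at -3.78, FABP4 at -3.72 and COCH at -2.60. Of these 118, 21 did not pass without at least 1 single array, and the omission of each of the 13 but contact-inhibited replicate 1 ended a call. Their highest limma adjusted p was NPM3 0.0711, INCENP 0.0820, HSP90AB1 0.0764, SLC2A1 0.102, RBL1 0.112, NDUFA8 0.0603, LDHB 0.0670, COCH 0.0758 and PRRX1 0.106 without serum-starved replicate 3; RFC3 0.107, CENPK 0.0881, NCAPG 0.0681 and LCP1 0.0640 without serum-starved replicate 2; VEGFA 0.0816, PHGDH 0.0839, ACAT2 0.0975, FDPS 0.0595 and HYOU1 0.0588 without confluent and starved replicate 1; HEXA 0.0854, F13A1 0.104 and LY86 0.0757 without confluent and starved replicate 2.

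Other splits of the arrays were counted for the pairwise comparisons. In contact-inhibited against cycling cells 1 of 35 splits, the real one, called as many as 9831 probe sets, and the highest other called 3037. This share is under 0.05, but it is the smallest that 35 splits allow and was not adjusted over the comparisons. The real split stands out, and chance is not excluded. The same holds for serum-starved against contact-inhibited cells (1 of 35, 5462 against 1491) and doubly arrested against contact-inhibited cells (1 of 35, 4867 against 1502). With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real and highest other counts were 4713 and 0 for serum-starved against cycling, 8390 and 0 for doubly arrested against cycling, and 272 and 1 for doubly arrested against serum-starved cells.

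Of the 689 probe sets without a chicken ID, which the comparisons above left out, 7 were higher in doubly arrested, 4 in serum-starved and 7 in contact-inhibited cells than in cycling cells, and 5, 0 and 2 were lower. The brightest had a signal of 7200 to 7932 in doubly arrested, 3888 to 7088 in serum-starved and 1304 to 1447 in cycling arrays, with 2639 in contact-inhibited replicate 1 and 1457 to 1676 in replicates 2 to 4.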

How the results depend on the processing

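The W-linked covariate and the joint removal of cycling replicate 3 and contact-inhibited replicate 1 were tests chosen only after the result was seen. Under settings other than the omission of an array, 218 counts and agreements stayed near their reported value and 37 moved, and 674 list results kept their call and direction while 96 lost the call. Under omissions 146 and 29 counts and agreements did so, and 416 and 41 list results. With array weights the higher and lower counts were 4504 and 3378 for serum-starved against cycling cells, 5070 and 3938 for serum-starved against contact-inhibited, 6006 and 4139 for doubly arrested against contact-inhibited, 2124 and 1571 against serum-starved, and 3901 and 3237 for the interaction. The lower count of doubly arrested against cycling cells was 5537 and the overlap of the 3 comparisons 4813. With both arrays removed the lower counts against contact-inhibited cells were 3391 and 2890, the doubly arrested against serum-starved counts 1101 and 918, and the interaction counts 2602 and 2227. With the W-linked covariate serum-starved cells had 1015 lower, doubly arrested cells 3174 and 1656 against cycling and 315 and 281 against serum-starved, the overlap was 1773 and the starvation effects correlated at 0.476. It kept 43.9% and 43.8% of the calls of the starved groups against cycling cells. A fit of the compared arrays alone gave 1803 higher in serum-starved cells, and 433 and 430 for doubly arrested against serum-starved. A replicate block gave 41 and 54 there and kept 88 of the 272 calls. Over all comparisons the block ended the call of 7 named gene comparisons and 1 list result. With an estimated correlation 0 lists passed in contact-inhibited, 0 in serum-starved, 0 in doubly arrested cells and 0 in the interaction. Fry, which tests a list against no change rather than against the other genes, called 25 and 22 in contact-inhibited and doubly arrested cells, and quantile normalization 10 in the interaction. The cause was not tested.

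Values of genes that had not passed changed sign as follows. CDKN1B in serum-starved cells was -0.10 with centred arrays, -0.12 with the W-linked covariate, and -0.0013, -0.043 and -0.049 without cycling replicates 1 and 2 and serum-starved replicate 3, in a range up to 0.11 over omissions. VEGFA was -0.12 with the covariate and -0.061 with both arrays removed or without cycling replicate 3, and in doubly arrested cells -0.14 and -0.036, with ranges over omissions up to 0.45 and 0.48. COL1A1 in serum-starved cells was -0.022 with centred arrays and -0.27 with the covariate, and -0.27 with the covariate in doubly arrested cells. The cause was not tested.

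Over omissions of an array the higher and lower counts ranged over 4210 to 5432 and 3846 to 4606 for contact-inhibited against cycling, 1518 to 2979 and 1034 to 1765 for serum-starved, and 3581 to 5089 and 2557 to 3205 for doubly arrested cells. Against contact-inhibited cells they were 2411 to 3314 and 1333 to 2347 in serum-starved, and 1958 to 2955 and 1110 to 2022 in doubly arrested cells. Doubly arrested against serum-starved cells gave 10 to 79 and 21 to 75, the interaction 1074 to 2002 and 829 to 1785, and the overlap 1720 to 3600. Lists passing numbered 13 to 16, 11 to 15, 10 to 11 and 13 to 16, and the agreements of effects were 0.314 to 0.404 and 0.301 to 0.340. Signal near the filter level limits what dim genes can show.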

Other observations

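The genes named here beyond those given above were chosen after their values were seen, and no test was added for them. The inflammatory list as a whole did not pass in contact-inhibited cells, where 11 of 33 genes rose and 6 fell (adjusted p = 0.218). Of its members NFKBIZ, TNFAIP3 and NFKBIA rose by 2.11 ± 0.22, 1.95 ± 0.29 and 1.5 ± 0.20, and the chemokine CXCL14 by 2.63 ± 0.30. The cytokines LIF and IL6 and the prostaglandin synthase PTGS2 fell (-2.88 ± 0.23, -2.04 ± 0.56 and -1.43 ± 0.26; IL6 -2.66 without contact-inhibited replicate 1, and not passing without cycling replicate 1, limma adjusted p = 0.0568). In serum-starved cells the same genes in this order had 1.51, 1.62, 0.78, 1.70, -1.17, -2.45 and 2.28.

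Of 12 cartilage genes 7 rose and 2 fell in contact-inhibited cells, and the list did not pass. The proteoglycan ACAN and the matrix protein COMP rose (3.44 ± 0.16 and 2.12 ± 0.10), whereas collagen II, COL2A1, and the link protein HAPLN1 fell (-3.52 ± 0.12 and -1.90 ± 0.29). Among muscle genes ACTC1, ACTA1, TNNC1 and TNNI2 fell (-3.57 ± 0.59, -2.23 ± 0.30, -1.76 ± 0.18 and -1.21 ± 0.21; ACTC1 -2.80 without contact-inhibited replicate 1) and the acetylcholine receptor genes CHRND and CHRNA1 rose (1.07 ± 0.24 and 0.69 ± 0.16). The adipocyte regulator PPARG rose by 0.91 ± 0.26, AGPAT2 by 1.37 ± 0.19 and CIDEC by 0.78 ± 0.23, which did not pass without cycling replicate 1 or 2 (limma adjusted p = 0.0517 and 0.0526). ACAN and TNFAIP3 in cycling cells and TNNI2 in contact-inhibited cells had a mean signal under the filter level of 22.7, so their folds depend on the offset. In the interferon list TLR3 and LY6E fell (-0.99 ± 0.24 and -1.2 ± 0.25) and IRF8 and EIF2AK2 rose (0.80 ± 0.18 and 0.75 ± 0.17).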
